A study of Mus musculus with 8 samples.

How the data were processed

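RNA was measured by poly(A)-selected, paired-end sequencing of 50 bp reads in 8 libraries from mouse bone marrow, 2 per group of LT-HSC WT, LT-HSC KO, MPP WT and MPP KO. Per the labels' protocols, cells were flow sorted from mice 20 weeks after transplant of WT or Tet1 KO marrow, and the growth protocol gives an age of 6 months. The sort gates are not given in the sources used here. Per the submitters' processing notes, CASAVA and TopHat were used with the mm9 build; versions, the read counter and the gene annotation are not stated there. The authors deposited 1 table per population with a raw count per Ensembl gene and library. The authors also deposited for each gene a log2 fold change of KO over WT and a mean log2 CPM per the file headers. The same tables hold the authors' likelihood ratio score and the authors' p-value and FDR per the file headers, without naming the tool. The count columns are named by genotype with a number before the replicate that the labels do not explain. Columns were matched to samples by genotype and replicate, and 0 columns of values per sample were left unmatched.

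The deposited tables list 19685 genes for LT-HSC and 18904 genes for MPP, with 0 counts in all libraries for 139 and 74 of them. Symbols come from the deposited tables, and 18518 and 17781 of the Ensembl IDs were also found in a current gene table, used only to match older symbols. Coordinates are those of the deposited tables on mm9. Total counts per library were 4976459 to 5479731 in LT-HSC and 11928659 to 12504581 in MPP. A count of 0 allows up to 0.547 to 0.603 CPM per LT-HSC library and 0.24 to 0.251 CPM per MPP library, taking 3 counts as the floor. Intervals and floors cover counting error only, since no molecular identifiers are described in the sources used here. Correlations of log CPM between the 2 libraries of a group were 0.973 (LT-HSC KO), 0.977 (LT-HSC WT), 0.986 (MPP KO) and 0.987 (MPP WT), against 0.839 to 0.869 and 0.962 to 0.973 between genotypes.

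The deposited counts were analysed per population with edgeR 4.0.16 in R 4.3.3: low counts filtered with filterByExpr, TMM normalization, and a quasi-likelihood test with Benjamini-Hochberg adjusted p-values under 0.05. This left 15684 genes in LT-HSC and 14902 in MPP, with a biological coefficient of variation of 0.185 and 0.107. The median log2 fold change of tested genes was 0.03 and -0.01, and -0.18 and -0.03 over abundant genes, at a mean log2 CPM above 6. The interaction of population and genotype used all 8 libraries over 16551 genes, and WT LT-HSC against WT MPP used the 4 WT libraries over 14660 genes. Genes with 0 counts in a group are given as a lower bound against 3 counts over the group, and genes with 1 to 3 counts as a ratio of normalized counts with a 95% exact binomial interval. Standard errors are the fold change divided by the square root of the test statistic. Overlaps were tested with Fisher's exact test, two-sided, with 4 tests adjusted together. DESeq2 1.42.0 served as a different tool. There were no shared control libraries between the populations.

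Lists, tests and the rule for named genes were fixed before the data were examined. The named genes were Tet1, the 12 largest rises and 12 largest falls per population among called genes with a mean of at least 50 normalized counts, a descriptive symbol and KO libraries on 1 side of both WT libraries, at most 4 called genes per list by fold change, and the 10 genes called in both populations with the largest fold changes, by the smaller of the 2, under the same limits on counts, symbol and libraries in each. Some genes that met this rule are not reported here. Globin genes, Tet2, Tet3, Mecom, Hlf, Mpo, Gm16869, Gm10800, Gm10801, the Xlr genes and the genes named in the WT comparison were chosen after their values were seen. The 19 fixed lists were TET and DNA methylation, LT-HSC identity, MPP and early lymphoid priming, B lineage, T and NK lineage, granulocyte and monocyte, erythroid, megakaryocyte, endothelial and stromal, replication-dependent histone, cell cycle, DNA repair, interferon response, immediate early and heat shock, ribosomal protein, Polycomb, genes mutated in B cell lymphoma, cytokine receptor and self-renewal signalling, and sex-linked check genes. Another 4 lists were added after the data were seen: antibody-secreting cell, bone-lining and osteoblast, germline and further erythroid genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move one way without comparing them with other genes.

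The tests were first run on simulated data with 200 changed genes. In LT-HSC (15684 genes) edgeR recovered 26% of genes changed 2-fold and 78% of those changed 4-fold, with 19 false among 123 calls. In MPP (14902 genes) it recovered 82% and 88%, with 31 false among 201. For the interaction (13747 genes) it recovered 25% and 77%, with 5 false among 107, and for the WT comparison (13747 genes) 56% and 88%, with 10 false among 154. False calls were 15.4% of edgeR calls in LT-HSC and in MPP, above the 5% that the threshold aims at. As many changes were simulated up as down, without a background that differs by genotype or deviations shared across groups. These rates may therefore not hold for the real counts. A simulated list with every member changed had an adjusted p of 0.047 in LT-HSC (15069 genes) and 0.0247 in MPP (14641 genes) under camera with an estimated correlation. The counts of replicate libraries differed beyond sampling noise, with a chi-square per gene of 10.4 to 14.9.

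Alternatives were DESeq2, upper quartile scaling, no filter and a stricter filter on counts, leaving out each library, the replicate number as a block, all 8 libraries in 1 fit, other thresholds, a 2-fold minimum and only genes with 1 entry per symbol. Alternatives chosen after the data were seen were subtraction of the background expected from gene span, genes with expected background under 10% of their counts, leaving out Gm16869, Gm10800 and Gm10801, leaving out immunoglobulin genes, and centring the median fold change on 0. The expected background of a library is its counts per kb of span in genes with at most 10 counts over the MPP libraries, at least 20 kb of span and fewer than 2000 counts over the LT-HSC libraries, times the span of each gene.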

Results

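Poly(A) RNA was sequenced from 8 libraries of mouse bone marrow cells isolated by flow sorting. They held 2 cell populations: long-term hematopoietic stem cells (LT-HSC), which can rebuild the blood for life, and multipotent progenitors (MPP), their more limited offspring. The mice had received bone marrow from wild-type (WT) or Tet1 knockout (KO) donors 20 weeks earlier. Tet1 encodes an enzyme that oxidizes 5-methylcytosine in DNA. There were 4 groups of 2 libraries: LT-HSC WT, LT-HSC KO, MPP WT and MPP KO. RNA came from 10000 LT-HSC or 100000 MPP per library. The total count per library was 4976459 to 5479731 in LT-HSC and 11928659 to 12504581 in MPP. Levels below are counts scaled to library size (CPM), as mean ± SD with n = 2 libraries. Fold changes are log2 KO over WT from edgeR with their standard error (SE), and adjusted p-values are from its quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. It is not given that the 2 libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

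Tet1 (ENSMUSG00000047146, chromosome 10, 62267318 to 62361866 on mm9) was examined first. In LT-HSC its counts were 336 and 379 in KO and 332 and 428 in WT, a log2 fold change of -0.09 (SE 0.19, adjusted p = 0.765). In MPP its counts were 765 and 855 in KO and 1207 and 1323 in WT, a log2 fold change of -0.62 (SE 0.09, adjusted p = 0.0282). Over the alternatives tried, its MPP adjusted p ran from 4.37e-41 (replicate number as a block) to 0.324 (without MPP WT replicate 1). Leaving out either WT library ended the call of every named MPP gene, and leaving out either KO library also ended that of Tet1. The part of the gene removed in the KO is not given in the sources used here, so a count over the whole gene is a weak check of the labels. In LT-HSC it does not separate the genotypes, and KO there means the libraries labelled KO throughout. The related enzymes Tet2 and Tet3 had log2 fold changes of -0.00 (SE 0.20) and -0.11 (SE 0.17) in LT-HSC and 0.28 (SE 0.09) and 0.08 (SE 0.07) in MPP, and neither passed the threshold in either population.

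All 4 Y-linked genes checked, Ddx3y, Eif2s3y, Kdm5d and Uty, were lower in the KO libraries of both populations. Ddx3y, an RNA helicase gene of the Y chromosome, had 26 and 30 counts in LT-HSC KO against 374 and 400 in WT, and 19 and 57 in MPP KO against 931 and 1002 in WT. Kdm5d, a histone demethylase gene, had 0 counts in both MPP KO libraries and 592 over the MPP WT libraries, at least 194-fold lower with 3 counts over the group as the floor. With an estimated correlation, the adjusted p of this list was 0.233 in LT-HSC and 0.0828 in MPP. All 4 genes were lower in every KO library than in any WT library, as a difference in sex would give. The fall was smallest for Uty in LT-HSC, with 34 and 35 counts in KO against 153 and 162 in WT. Xist, which was also on this list, is in neither deposited table, so it could not be checked. The sex of the donors and of the recipients is not given in the sources used here, and this difference coincides with genotype in both comparisons. An effect of sex can therefore not be told apart from one of genotype in any KO against WT result here.

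The comparison of LT-HSC KO with WT asks which transcripts differ between stem cells from donor marrow labelled Tet1 KO and WT. Red cell genes rose together: all 15 measured erythroid genes were higher in KO, with a median log2 fold change of 2.15. Klf1, the master transcription factor of red cell formation (ENSMUSG00000054191, chromosome 8, 87425827 to 87429194), was at 130.5 ± 4.93 CPM in KO and 9.81 ± 2.54 CPM in WT, a log2 fold change of 3.73 (SE 0.22). Ermap rose by 3.89 (SE 0.18) and Car1, a carbonic anhydrase gene, by 3.28 (SE 0.31). The globin genes rose less, by 2.07 (SE 0.29) for Hba-a1 and 1.75 (SE 0.41) for Hbb-b1. Each has a near-identical neighbour (Hba-a2 and Hbb-b2), so how reads divide within a pair is uncertain. The preset-correlation camera test gave an adjusted p of 1.28e-15 for the list, and adjusted p = 0.233 with an estimated correlation. The background reads described below account for a median of 0.223% of the excess of the erythroid genes called higher in KO.

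Endothelial and stromal genes formed the other list called higher in LT-HSC KO: 8 of 12 rose and 4 did not pass, with a median of 3.34. The 4 were the endothelial genes Pecam1 (-0.33), Kdr (0.33) and Emcn (-0.05) and the stromal gene Pdgfrb (0.35). Col1a1, the main collagen of bone (ENSMUSG00000001506, chromosome 11, 94797538 to 94814356), was at 271 ± 71.9 CPM in KO against 1.06 ± 0.42 CPM in WT, a log2 fold change of 7.97 (SE 0.34). Cxcl12, a chemokine of the stem cell niche, had 75 counts in KO and 0 in WT, at least 25-fold higher, Col3a1 had 44 against 1, a ratio of 44.1 (95% interval 7.51 to 1780), and Lepr, a receptor of niche cells, rose by 4.97 (SE 0.72). Among all genes, the rises included Prg4, which encodes a joint lubricant, at least 132-fold higher, Bglap, which encodes the bone protein osteocalcin, at least 82.1-fold higher, and Ccnb1ip1, a gene of meiotic recombination, at least 68.5-fold higher. The camera adjusted p of the stromal list was 1.32e-05, and 0.233 with an estimated correlation, and the background accounts for a median of 27.8% of the excess of the members that rose. With it subtracted 5 of these 8 still rose (Col1a1, Col1a2, Sparc, Lepr and Cxcl12), while Flt1, Col3a1 and Cdh5 had too few counts left for a test. The 5 are stromal genes, so no endothelial member was shown to rise beyond the background. Of the other 8 of the 12 largest rises among genes with a descriptive symbol and a mean of at least 50 normalized counts, Rbfox3, Fstl4, Cnbd1, Tmeff2, Fam19a2 and Kcnd2 span long stretches of DNA, where the background described below weighs most. Rbfox3, a splicing factor gene of neurons, had 198 counts in KO and 2 in WT (ratio 99.2, 95% interval 27.1 to 825), and Fstl4 had 285 and 3 (ratio 95.2, 95% interval 32.2 to 464). Cnbd1, Slc6a20a and Tmeff2 had ratios of 84.5, 76.8 and 68.1, and Fam19a2, Hrsp12 and Kcnd2 had log2 fold changes of 6.07, 5.85 and 5.85.

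Immediate early genes, which switch on within minutes of a stimulus, fell in LT-HSC KO: 17 of the 22 immediate early and heat shock genes fell and 5 did not pass. Klf2, a factor linked to cell quiescence, was at 111.2 ± 3.97 CPM in KO and 623.9 ± 34.3 CPM in WT, a log2 fold change of -2.49 (SE 0.16). Klf4, Egr2 and Jun, all transcription factor genes, had log2 fold changes of -1.94 (SE 0.18), -2.38 (SE 0.33) and -1.21 (SE 0.20). Without KO replicate 1 the Jun call ended (adjusted p = 0.0543). Adjusted over the list alone, 1 rose and 19 fell. The list's median was -0.86, its camera adjusted p was 2.02e-09, and with an estimated correlation the adjusted p was 0.233. Megakaryocyte genes, of the lineage that makes platelets, were lower in 8 of 11 cases with a median of -1.07 (camera adjusted p = 5.22e-06, adjusted p = 0.233 with an estimated correlation). Itga2b, the platelet integrin known as CD41, went from 531.9 ± 121 to 191.8 ± 41.9 CPM, a log2 fold change of -1.47 (SE 0.22), and Gp1bb, Treml1 and Pf4 had -2.35, -2.11 and -1.27. Erythroid and stromal genes and background reads were higher in the same KO libraries. With the background described below subtracted, the immediate early and megakaryocyte medians were -0.67 and -0.91 (camera adjusted p = 2.79e-08 and 1.39e-05).

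LT-HSC identity genes leaned lower: 11 of 26 fell, 15 did not pass, and 14 fell when adjusted over the list alone. Vwf, a marker of platelet-biased stem cells, was at 203.8 ± 14.1 CPM in KO and 456.6 ± 72.2 CPM in WT, a log2 fold change of -1.16 (SE 0.17). Esam, an adhesion gene of stem cells, had -1.32 (SE 0.18), Ly6a, which encodes the stem cell marker Sca-1, had -1.32 (SE 0.40), and Ndn had -1.44 (SE 0.46). The Ly6a call ended without KO replicate 2 (adjusted p = 0.138; 2.32e-14 to 0.151 over the alternatives). The Ndn call ended without any 1 library, at adjusted p = 0.0611, 0.0895, 0.251 and 0.212 without WT replicates 1 and 2 and KO replicates 1 and 2. The stem cell genes Mecom and Hlf had log2 fold changes of -0.16 (SE 0.16) and 0.25 (SE 0.18) and did not pass. The list's camera adjusted p was 3.12e-05, and 0.233 with an estimated correlation. Erythroid and stromal genes and background reads were higher in the same KO libraries, and with the background described below subtracted the Ly6a and Ndn calls ended (adjusted p = 0.109 and 0.133) while the list passed (0.000736).

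Of 26 cell cycle genes 8 rose in LT-HSC KO and 18 did not pass, with 0 lower by edgeR (0 lower at an unadjusted p under 0.05 and 0 by DESeq2). The list did not pass camera (adjusted p = 0.233, and 0.663 with an estimated correlation), but passed with the background described below subtracted (0.000163). All 15 erythroid genes rose in the same libraries, and the cell type in which the cell cycle genes rose was not tested. Ccne1 and Ccne2, the E cyclins that drive entry into DNA replication, rose by 3.48 (SE 0.21) and 1.84 (SE 0.28), Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose by 1.39 (SE 0.28) and Ccnb1 by 1.15 (SE 0.25). The Rrm2 call ended without KO replicate 1 (adjusted p = 0.0511) and the Ccnb1 call without KO replicate 2 (0.0716). Cdkn1a, the cell cycle brake p21, had a log2 fold change of -1.93 (SE 0.18), from 281.8 ± 31.6 to 74.1 ± 9.83 CPM. It belongs to the list of cytokine receptor and self-renewal signalling genes, of which 3 rose and 6 fell among 24 (3 and 7 over the list alone), with Csf2rb2 at -1.70 (SE 0.28) and Lef1 at 79 counts in KO against 3 in WT (ratio 26.4, 95% interval 8.7 to 131). Cdkn2a had 27 against 2 (ratio 13.5, 95% interval 3.4 to 117), a call that ended without WT replicate 1, KO replicate 1 or KO replicate 2 (adjusted p = 0.101, 0.0981 and 0.101). The DNA repair list had 7 higher and 2 lower among 47, with Fancc at 1.51, Msh3 at 0.99, Blm at 0.73 and Fancg at -0.96, and it did not pass camera (adjusted p = 0.47); over the list alone 4 rose and 1 fell. Among members that rose, the background accounts for a median of 48.2% of the excess of cytokine receptor genes (89.5% for Lef1) and 31.7% for DNA repair genes (70.6% for Fancc). With it subtracted, Lef1 and Cdkn2a had too few counts left for a test and the calls of Fancc (0.91, adjusted p = 0.154) and Fancg (-0.83, 0.0555) ended. Without KO replicate 1 or 2 the calls of Msh3 (adjusted p = 0.0599 and 0.0778), Blm (0.0722 and 0.109) and Fancg (0.0789 and 0.144) ended.

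Among the remaining lists, interferon response genes had 2 higher and 7 lower among 25 in LT-HSC KO (camera adjusted p = 0.0051), with Gbp2 at -1.30 (SE 0.22) and Bst2 at -1.01 (SE 0.24) but Xaf1 at 1.36 (SE 0.21) and Usp18 at 1.25 (SE 0.29). Polycomb genes, which encode a repressor of developmental genes, had 4 lower among 19 (camera adjusted p = 0.0327), with Phf19 at -1.40, Ezh1 at -0.78, Phf1 at -0.75 and Mtf2 at -0.59, and 3 over the list alone. Genes mutated in B cell lymphoma had 2 higher and 5 lower among 19 (camera adjusted p = 0.0302), with Tnfaip3, a brake on NF-kB signalling, at -1.45 (SE 0.15), Id3 at -2.64 (SE 0.35) and Prdm1 at 2.02 (SE 0.55). The cytokine receptor list had a camera adjusted p of 0.0302, and with an estimated correlation these 4 lists each had adjusted p = 0.233. With the background described below subtracted, all 4 calls ended. These were interferon response (adjusted p = 0.0962, median from -0.55 to -0.44), Polycomb (0.314, -0.33 to -0.15), lymphoma (0.0992, -0.14 to -0.11) and cytokine receptor genes (0.0615, -0.31 to -0.17). The cytokine receptor list call also ended without KO replicate 1 (0.0665), and the Polycomb and lymphoma list calls without KO replicate 2 (0.0628 and 0.116). Lineage lists went both ways and did not pass camera: B lineage genes had 7 higher and 3 lower among 17 (adjusted p = 0.47), T and NK genes 3 and 2 among 8 (0.408), granulocyte and monocyte genes 6 and 1 among 16 (0.268), and MPP and early lymphoid priming genes 3 and 4 among 11 (0.233). Named members were Cr2 at 4.02, Bank1 at 2.02, Ebf1 at 2.00, Cd79b at -1.67, Bcl11b at 2.77, Klrb1c at -2.39, Ccr9 at 2.14, Cd48 at -1.55 and Flt3 at 0.76, with ratios of 11.7 (3.68 to 59.4) for Blk, 45.1 (7.69 to 1820) for Cd2, 50.1 (8.59 to 2020) for Fcgr3 and 9.68 (3 to 49.7) for Ltf. Among members that rose, the background accounts for a median of 77.9% of the excess of B lineage, 41.3% of T and NK, 24.1% of priming and 4.58% of granulocyte and monocyte genes. With it subtracted Ebf1 became -0.36, the calls of Bank1, Bcl11b and Cd48 ended (adjusted p = 0.181, 0.206 and 0.0927), and Ccr9, Blk, Cd2 and Ltf had too few counts left for a test. The neutrophil genes Ngp and S100a8 were at least 28-fold and at least 20-fold higher. Histone genes had 2 higher and 3 lower among 59, and 0 by edgeR over the list alone (11 at an unadjusted p under 0.05; DESeq2 1 and 2; Hist1h1b at 1.1, Hist4h4 at -2.14, Hist1h2ae at -1.0, Hist1h3a at -0.79), and the TET and DNA methylation genes 1 and 1 among 13 (Mbd4 at 1.14 and Gadd45b at -2.08). Of 72 ribosomal protein genes, Rpl22 fell (-0.55, SE 0.18), a call that ended over the list alone and without WT replicate 2, KO replicate 1 or KO replicate 2 (adjusted p = 0.131, 0.352 and 0.122). The ribosomal list passed camera without WT replicate 1 (adjusted p = 4.4e-06) or KO replicate 2 (0.00195), and the histone list without WT replicate 1 (0.046) or 2 (0.0354). Leaving out KO replicate 1 also ended the calls of Prdm1 (adjusted p = 0.293), Phf19 (0.0909), Mbd4 (0.109), Ccr9 (0.2) and Bcl11b (0.0781). Leaving out KO replicate 1 or 2 ended those of Usp18 (0.0599, 0.09), Bst2 (0.0592, 0.13), Ezh1 (0.0865, 0.167), Mtf2 (0.202, 0.189), Cd79b (0.0735, 0.0509), Klrb1c (0.0609, 0.0571), Flt3 (0.226, 0.0861), Hist1h1b (0.12, 0.101), Hist1h2ae (0.07, 0.169), Hist1h3a (0.113, 0.183), and, with 1 of the WT libraries as well, Phf1 (0.147 without WT replicate 1, 0.154, 0.22), Cd48 (0.0763 without WT replicate 1, 0.298, 0.111), Hist4h4 (0.0606 without WT replicate 1, 0.0914, 0.238) and Ltf (0.0679 without WT replicate 2, 0.0885, 0.0995). Under the limits on symbol and counts used for the rises, the largest falls outside the Y-linked genes were in Ighg1, an antibody heavy chain constant region, at -7.31 (SE 0.49), Igkv4-72 (1 count against 265), Ighv1-61 at -3.47 (SE 0.57), Vill at -3.58 (SE 0.30), Gbp1 at -3.51 (SE 0.40), the Wnt receptor Fzd8 at -3.28 (SE 0.34), Ncf4 at -3.09 (SE 0.32), Nkg7 at -3.08 (SE 0.22) and Xlr4a at -2.74 (SE 0.46).

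**Figure D1:**
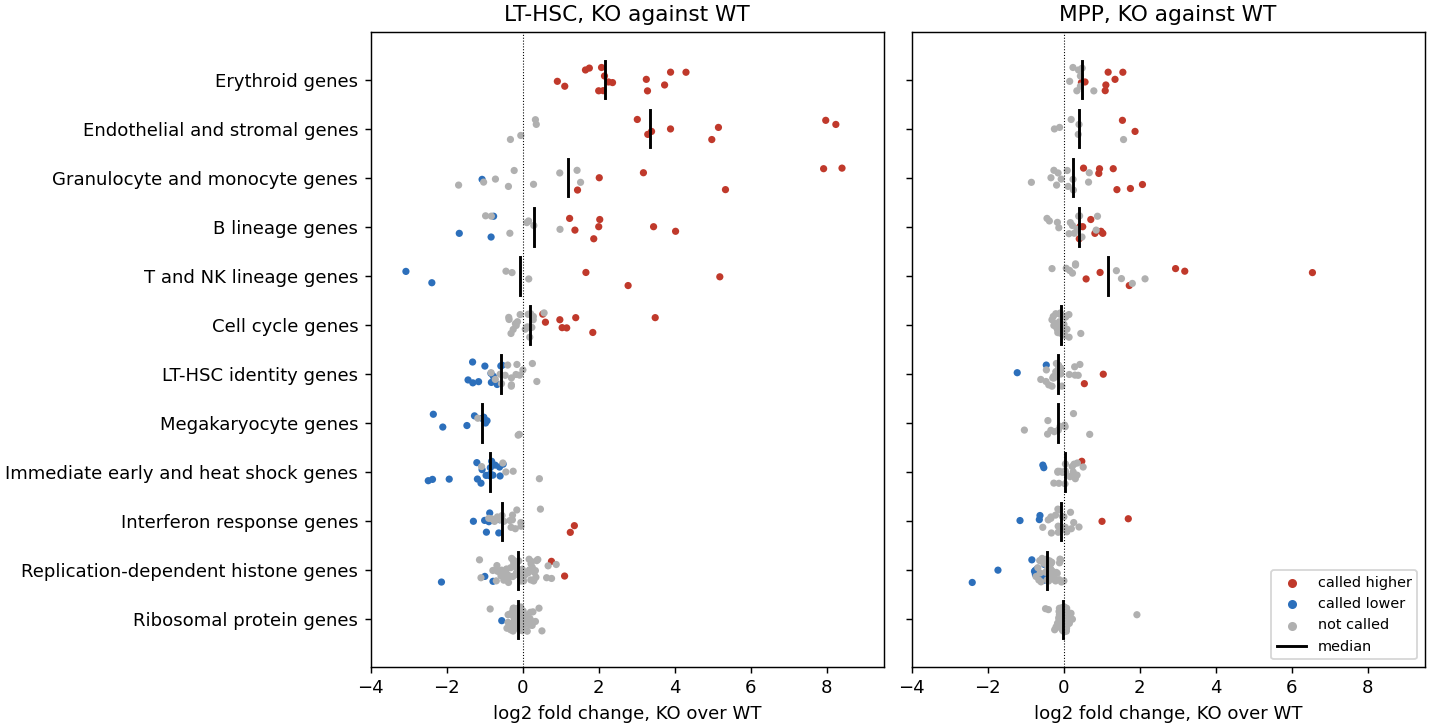
Log2 fold changes of the members of 12 gene lists, KO over WT, in LT-HSC (left) and MPP (right); points are genes, red and blue mark genes called higher and lower at an adjusted p under 0.05, and bars are list medians. All 15 erythroid genes lie above 0 in LT-HSC, and 17 of 22 immediate early and heat shock genes are called lower there.

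In LT-HSC, 3529 of the 15684 genes tested were higher in KO and 1717 were lower. The authors' deposited FDR gave 5418 higher and 1668 lower under 0.05. With the replicate number as a block, 4815 were higher and 4009 lower. The KO libraries also carried far more background reads. The 3 satellite-rich genes Gm16869, Gm10800 and Gm10801 took 7.68% and 9.87% of KO counts against 0.181% and 0.213% of WT counts. In MPP they took a far smaller share, 0.00574% and 0.00572% in KO against 0.0033% and 0.00313% in WT. Gm16869 (log2 fold change 0.99) and Gm10800 (0.93) were called higher in MPP KO as well. Genes with at most 10 counts over the MPP libraries and a span of at least 20 kb held 0.349 and 0.319 counts per kb of span in the KO libraries against 0.0311 and 0.0401 in WT, and their counts grew with span in KO. With the background expected from span subtracted, 1298 genes were higher and 850 lower. Among genes whose expected background was under 10% of their counts, 449 were higher and 303 lower. The subtraction of background reversed the sign of 2 named genes, Ebf1 (-0.36) and Ptprd (-1.12), neither of which then passed, and kept Klf1 at 3.91, Klf2 at -2.31 and Cdkn1a at -1.75. It ended the calls of 16 named genes. In 7 of them the SE grew. Ndn went from -1.44 (SE 0.46) to -1.39 (SE 0.55), Cd48 from -1.55 (SE 0.49) to -2.93 (SE 1.01), Bcl11b from 2.77 (SE 0.64) to 2.23 (SE 1.08). Hist4h4 went from -2.14 (SE 0.57) to -1.96 (SE 0.68), Ighv1-19 from 1.97 (SE 0.65) to 2.16 (SE 0.71), Bank1 from 2.02 (SE 0.30) to 1.13 (SE 0.51) and Fancc from 1.51 (SE 0.28) to 0.91 (SE 0.39). In the other 9 the fold shrank by less than 1 SE at a similar SE. Ly6a went from -1.32 (SE 0.40) to -1.13 (SE 0.41), Hist1h2ae from -1.0 (SE 0.27) to -0.81 (SE 0.27), Hist1h3a from -0.79 (SE 0.21) to -0.60 (SE 0.20), Fancg from -0.96 (SE 0.24) to -0.83 (SE 0.24). Bst2 went from -1.01 (SE 0.24) to -0.84 (SE 0.23), Rpl22 from -0.55 (SE 0.18) to -0.38 (SE 0.19), Ezh1 from -0.78 (SE 0.20) to -0.67 (SE 0.20), Phf1 from -0.75 (SE 0.23) to -0.58 (SE 0.23) and Mtf2 from -0.59 (SE 0.16) to -0.46 (SE 0.16). All 9 of these genes were lower in KO. Across tested genes the subtraction raised the log2 fold change by a median of 0.132. Such a general shift shrinks falls and enlarges rises, as for Klf1 (3.73 to 3.91). The end of these 9 calls therefore does not show background reads in those genes. List medians given with the background subtracted include this shift. Another 14 named calls had too few counts left for a test: Rbfox3, Fstl4, Fam19a2, Tmeff2, Kcnd2, Ccr9, Blk, Cd2, Ltf, Col3a1, Prdm1, Lef1, Cdkn2a and Ncald. Leaving out 1 library gave 1946 to 4213 higher and 379 to 2543 lower genes, with 1946 and 379 without KO replicate 1 and 487 lower without KO replicate 2.

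**Figure D2:**
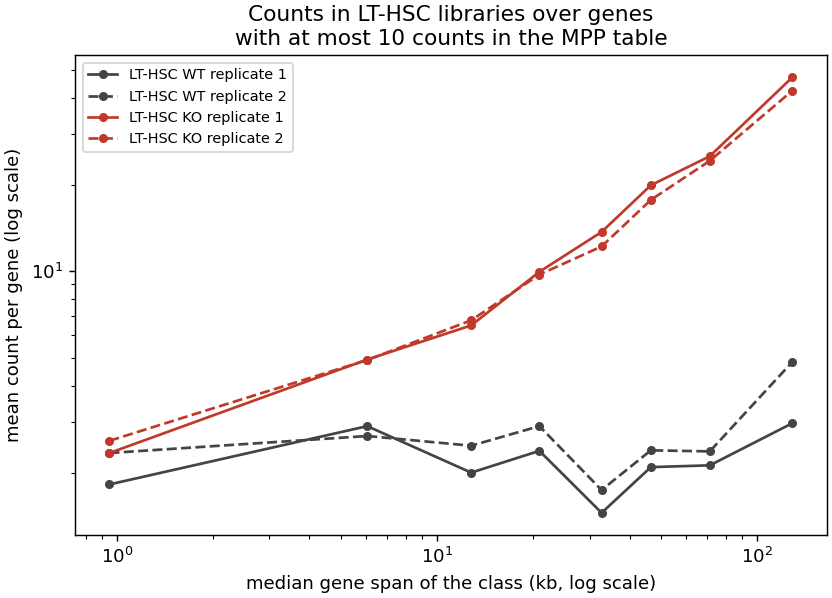
Mean count per gene (log scale) in each LT-HSC library over 8 classes of gene span (median span in kb, log scale), for genes with at most 10 counts over the MPP libraries. In the longest class, the KO libraries hold 47.2 and 42.4 counts per gene and the WT libraries 2.97 and 4.85.

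The comparison of MPP KO with WT asks the same of multipotent progenitors. Immunoglobulin transcripts gave all 12 of the largest rises among genes with a descriptive symbol and a mean of at least 50 normalized counts. Immunoglobulin genes took 9.73% (95% exact binomial interval 9.71 to 9.74) and 9.15% (9.14 to 9.17) of counts in MPP KO against 3.85% (3.84 to 3.86) and 3.68% (3.67 to 3.69) in WT. These intervals cover counting error only. Of 205 variable segments tested, 95 rose and 25 fell, and of 9 constant regions 6 rose and 1 fell. Ighv2-6, a heavy chain variable segment (ENSMUSG00000076642, chromosome 12, 114954886 to 114955314), was at 1839 ± 395 CPM in KO and 15.4 ± 3.16 CPM in WT, a log2 fold change of 6.90 (SE 0.25). Ighg3, the constant region of an IgG antibody, was at 1366 ± 175 against 85.9 ± 3.52 CPM, a log2 fold change of 3.99 (SE 0.12). Igkv8-27, a light chain segment, rose by 4.24 (SE 0.11), and the other 9 of the 12 largest rises were Igkv14-100, Ighv7-4, Ighv7-3, Ighv1-31, Ighv1-47, Igkv2-116, Igkv2-109, Ighv13-2 and Ighv1-85 (3.85 to 6.39), while Igkv1-88 had -4.12 (SE 0.14), Ighv14-2 -2.70 (SE 0.26), Ighv3-2 -3.43 (SE 0.26) and Igkv1-99 -3.29 (SE 0.11). Variable segments resemble each other, so how reads divide among them is uncertain.

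B lineage genes rose with them in MPP KO: 7 of 21 rose and 14 did not pass, and 15 rose and 1 fell when adjusted over the list alone. Pou2af1, a B cell coactivator, was at 343.5 ± 13.1 CPM in KO and 193.9 ± 11.2 CPM in WT, a log2 fold change of 0.83 (SE 0.08), and the surrogate light chain genes Vpreb1 and Igll1 had 1.03 (SE 0.19) and 0.99 (SE 0.13), and Blnk had 0.72 (SE 0.10). T and NK genes rose in 6 of 16 cases, though at low levels: Klrd1, a receptor of NK cells, was at 6.77 ± 0.42 against 2.03 ± 0.01 CPM, and Cd8a had 23 counts in KO and 0 in WT, at least 7.78-fold higher. Cd3g and Cd8b1 rose by 3.19 (SE 0.41) and 2.95 (SE 0.52), and over the list alone 10 rose and 1 fell. The camera adjusted p was 5.14e-05 for the B list and 6.24e-06 for the T and NK list, and 0.266 for each with an estimated correlation. Prdm1, the master regulator of antibody-secreting cells, rose by 1.71 (SE 0.08), and it belongs to the 19 genes mutated in B cell lymphoma, of which 3 rose, with Sgk1 at 0.50 (camera adjusted p = 0.24; over the list alone 4 rose and 2 fell). Il7r, a cytokine receptor of lymphoid progenitors, rose by 1.1 (SE 0.11) and Cd34 fell by 0.40 (SE 0.06), the 2 called among 12 MPP and early lymphoid priming genes (camera adjusted p = 0.533; over the list alone 3 rose and 4 fell).

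Granulocyte and erythroid genes also rose in MPP KO. Of 19 granulocyte and monocyte genes 7 rose and 12 did not pass: Elane, the neutrophil elastase gene (ENSMUSG00000020125, chromosome 10, 79349057 to 79350961), was at 354 ± 5.17 CPM in KO against 104.5 ± 5.95 CPM in WT, a log2 fold change of 1.76 (SE 0.07). Cebpe, a factor of late granulocyte maturation, rose by 2.08 (SE 0.20), Mpo, the myeloperoxidase gene, by 0.93 (SE 0.07), Ngp by 1.40 (SE 0.27) and S100a8 by 1.31 (SE 0.19). Over the list alone 9 rose and 1 fell. Of 15 erythroid genes 7 rose and 8 did not pass: Rhag rose by 1.56 (SE 0.10), Tspan33 by 1.36 (SE 0.11), Ermap by 1.17 (SE 0.08) and Klf1 by 1.11 (SE 0.12), 10 rose over the list alone, and Hba-a1 at 0.44 (SE 0.19) did not pass. The camera adjusted p was 6.24e-06 for the granulocyte list and 4.39e-11 for the erythroid list, and with an estimated correlation 0.536 and 0.392. Of 8 endothelial and stromal genes 2 rose, Col1a2 by 1.88 (SE 0.25) and Cdh5 by 1.55 (SE 0.15), and the list did not pass (camera adjusted p = 0.0778, and 0.0444 without WT replicate 2; over the list alone 3 rose and 1 fell).

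Replication-dependent histone genes fell in MPP KO: 18 of 60 fell and 42 did not pass, and 34 fell when adjusted over the list alone. Hist1h4f and Hist1h2bb, genes of the core histones H4 and H2B, had log2 fold changes of -0.83 (SE 0.12) and -0.76 (SE 0.10), Hist4h4 had -1.72 (SE 0.18) and Hist3h2bb-ps had -2.40 (SE 0.46). The list's median was -0.43, with a camera adjusted p of 1.59e-14 and adjusted p = 0.472 with an estimated correlation. Most of these transcripts carry no poly(A) tail, and family members are near-identical, so their counts after poly(A) selection are uncertain. Immunoglobulin, granulocyte and erythroid genes rose in the same KO libraries, and the cell type in which the histone genes fell was not tested. Outside the Y-linked and immunoglobulin genes, the largest falls among genes with a descriptive symbol and a mean of at least 50 normalized counts were in Lhfp at -4.09 (SE 0.18), Ccr1, a chemokine receptor gene, at -2.55 (SE 0.21), Hormad2, a meiotic gene, at -2.37 (SE 0.22) and Ccdc21 at -2.22 (SE 0.18). Among stem cell genes Slamf1, which encodes the marker CD150, and Gata2 had -1.22 (SE 0.16) and -0.45 (SE 0.07), while Mycn had 1.05 (SE 0.12), and 4 were called among 25 (camera adjusted p = 0.344; over the list alone 3 rose and 5 fell).

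Cdkn1a had a log2 fold change of -0.59 (SE 0.07) in MPP and Axin2, a target of Wnt signalling, -2.28 (SE 0.35), while Lef1, a factor of the same pathway, rose by 1.26 (SE 0.11). They belong to the 4 genes called among 23 cytokine receptor and self-renewal signalling genes (camera adjusted p = 0.775; over the list alone 2 rose and 3 fell). Interferon response genes had 2 higher and 3 lower among 26 (camera adjusted p = 0.344; over the list alone 2 rose and 6 fell), with Xaf1 at 1.70 (SE 0.10), Rsad2 at 1.01 (SE 0.16), Iigp1 at -1.14 (SE 0.15) and Oasl2 at -0.64 (SE 0.09). Fos rose by 0.48 (SE 0.09) while Atf3 and Ier3 had -0.54 and -0.52 among 22 immediate early and heat shock genes (camera adjusted p = 0.533; over the list alone 8 rose and 2 fell). Cbx7 rose by 0.76 (SE 0.10) among 19 Polycomb genes (adjusted p = 0.826), and Tet1 was the gene called among 13 TET and DNA methylation genes (adjusted p = 0.344). By edgeR 0 of 11 megakaryocyte, 0 of 26 cell cycle, 0 of 48 DNA repair and 0 of 73 ribosomal protein genes passed, with 2, 5, 10 and 2 under an unadjusted p of 0.05 and 0 in each list by DESeq2. The ribosomal list passed camera without WT replicate 1 (adjusted p = 0.00378), WT replicate 2 (0.042) or KO replicate 2 (0.0035).

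**Figure D3:**
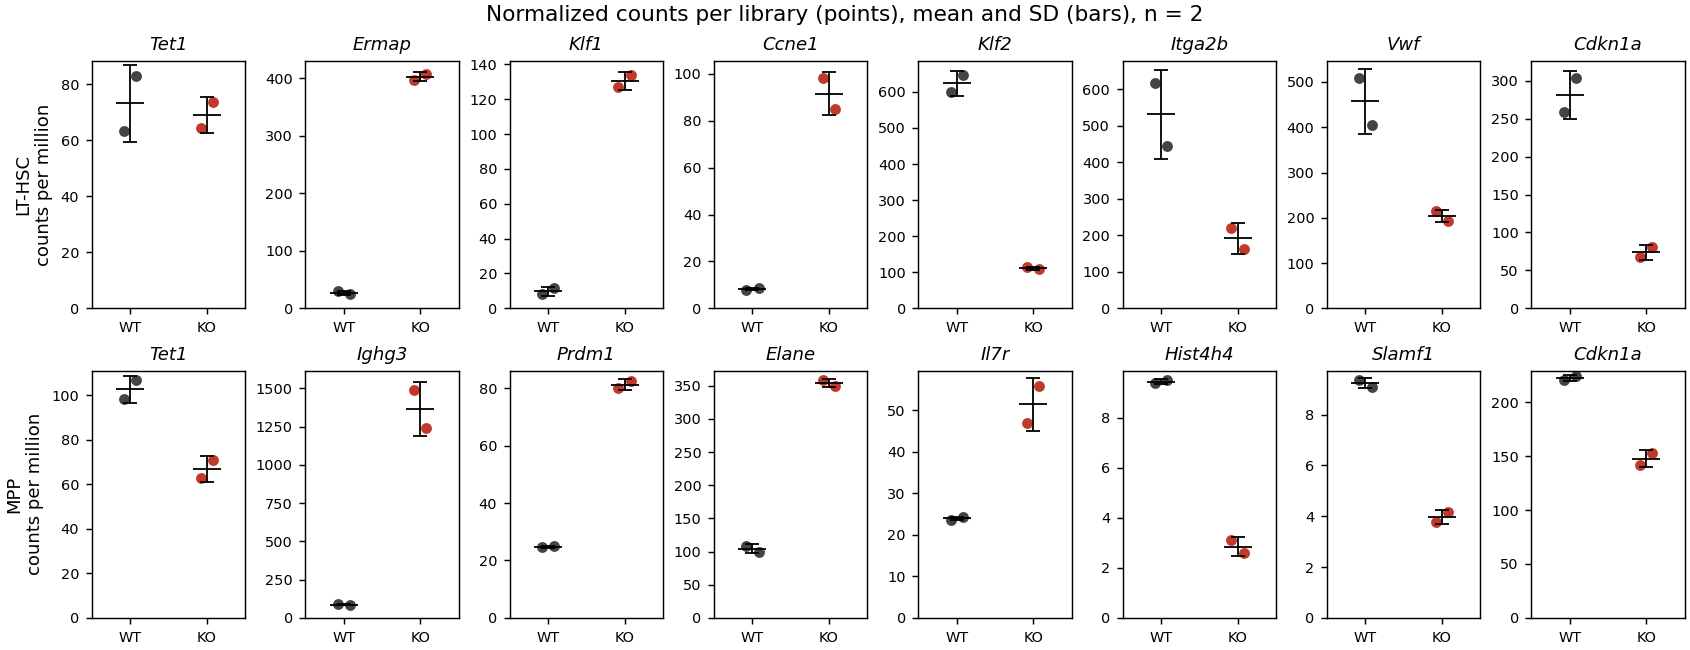
Normalized CPM of 8 genes in LT-HSC (top) and 8 genes in MPP (bottom); points are libraries, and bars are the mean and SD of n = 2 WT or KO libraries. The 2 KO libraries lie on the same side of both WT libraries for every gene shown except Tet1 in LT-HSC, where 336 and 379 KO counts overlap 332 and 428 WT counts.

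In MPP, 707 of the 14902 genes tested were higher in KO and 366 were lower, and the authors' deposited FDR gave 1006 higher and 487 lower under 0.05. With the replicate number as a block, 3536 were higher and 3698 lower, so the lean towards higher genes was not kept. What libraries of the same number share is not given in the sources used here. Without either MPP WT library the edgeR count was 0 in both directions, with 2119 genes (without WT replicate 1) and 2220 genes (without WT replicate 2) at an unadjusted p under 0.05. DESeq2 then gave 219 higher and 42 lower, and 203 higher and 53 lower. Without KO replicate 1 the edgeR counts were 213 and 55, and without KO replicate 2 they were 201 and 46. The edgeR fits without 1 WT library ended every named MPP call, even that of Kdm5d (0 counts in KO, 592 in WT). That outcome did not depend on the size of a change, so it cannot show that a call rests on either WT library. Without KO replicate 1 or 2 the calls of these genes also ended (adjusted p without each in turn): Slamf1 (0.0901, 0.0745), Mycn (0.0786, 0.066), Gata2 (0.121, 0.184), Cd34 (0.148, 0.173), Vpreb1 (0.143, 0.14), Igll1 (0.0884, 0.0614), Blnk (0.0928, 0.0643), Cd3g (0.0833, 0.0877), Cd8b1 (0.122, 0.0594), Klrd1 (0.061, 0.0691), Ngp (0.176, 0.159), S100a8 (0.121, 0.0939), Col1a2 (0.0956, 0.066), Hist3h2bb-ps (0.0786, 0.154), Hist1h4f (0.0737, 0.11), Hist1h2bb (0.0937, 0.0752), Iigp1 (0.0778, 0.052), Rsad2 (0.116, 0.125), Oasl2 (0.121, 0.0917), Atf3 (0.112, 0.101), Ier3 (0.107, 0.104), Fos (0.129, 0.204), Cbx7 (0.0805, 0.102), Sgk1 (0.132, 0.128), Axin2 (0.104, 0.14) and Cdkn1a (0.0915, 0.0715). Those of Pou2af1 and Hist4h4 ended without KO replicate 2 (adjusted p = 0.0511 and 0.0511), and those of Cebpe, Klf1 and Cdh5 without KO replicate 1 (0.0504, 0.061 and 0.051). Elane, Prdm1, Il7r, Ermap, Rhag, Tspan33, Xaf1, Lef1, Lhfp, Ccr1, Hormad2, Ccdc21 and the named Y-linked and immunoglobulin genes held without either KO library, and Cd8a had no value there.

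The overlap of the populations asks which genes changed in both, over 13747 genes tested in each. Among genes called in both with a descriptive symbol and a mean of at least 50 normalized counts in each, the 10 with the largest fold changes, by the smaller of the 2, were the Y-linked Eif2s3y, Kdm5d, Ddx3y and Uty, then Ncald, Vill, Hpn, Ltbp1, Ighv1-19 and Ptprd. Vill, a relative of the actin-binding gene villin, had log2 fold changes of -3.58 (SE 0.30) in LT-HSC and -2.14 (SE 0.13) in MPP. Ncald, a neuronal calcium sensor gene, had 3.65 (SE 0.37) and 2.33 (SE 0.20), Hpn, a membrane serine protease gene, 2.73 (SE 0.26) and 2.11 (SE 0.18), and Ltbp1, a TGF-beta binding protein gene, 3.52 (SE 0.30) and 2.03 (SE 0.23). The background is expected to give 114% of the LT-HSC excess of Ncald, which had too few counts left for a test with it subtracted, 57.6% for Ltbp1 and 2.77% for Hpn. Ptprd, a receptor phosphatase gene, rose by 2.03 (SE 0.18) in LT-HSC and had -1.96 (SE 0.20) in MPP, but its LT-HSC value became -1.12 with the background subtracted. The Ighv1-19 call in LT-HSC ended without KO replicate 1 (adjusted p = 0.221; 2.53e-09 to 0.221 over the alternatives), and the MPP calls of Ptprd and Ltbp1 ended without KO replicate 2 (0.055 and 0.0622). In the same direction, 224 genes were higher in both (76.6 expected if the lists were independent, Fisher's exact test, two-sided, p = 7.23e-57, adjusted p = 2.89e-56) and 129 were lower in both (37.2 expected, p = 7.68e-41, adjusted p = 1.54e-40). In opposite directions, 27 were higher in LT-HSC and lower in MPP (43.4 expected, Fisher's exact test p = 0.00604, adjusted p = 0.00805), and 47 the reverse (65.6 expected, p = 0.0106, adjusted p = 0.0106). Fisher's exact test takes genes as independent, and genes that move together are not, so these p-values can overstate the evidence. Libraries with the same replicate number also shared deviations between the populations (r = 0.49 to 0.533), so the 2 comparisons may not be independent. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.277 and a Spearman correlation of 0.223. With the LT-HSC background subtracted, 138 were higher and 96 lower in both, and with the replicate number as a block 1078 were higher and 1513 lower. Without LT-HSC KO replicate 1, 142 were higher and 61 lower in both, and without LT-HSC KO replicate 2, 68 were lower. Without MPP KO replicate 1 these counts were 77 and 24, without MPP KO replicate 2 they were 68 and 18, and without MPP WT replicate 1 or 2 they were 0, since edgeR then called 0 genes in MPP (2119 and 2220 at an unadjusted p under 0.05; DESeq2 219 higher and 42 lower, 203 higher and 53 lower).

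**Figure D4:**
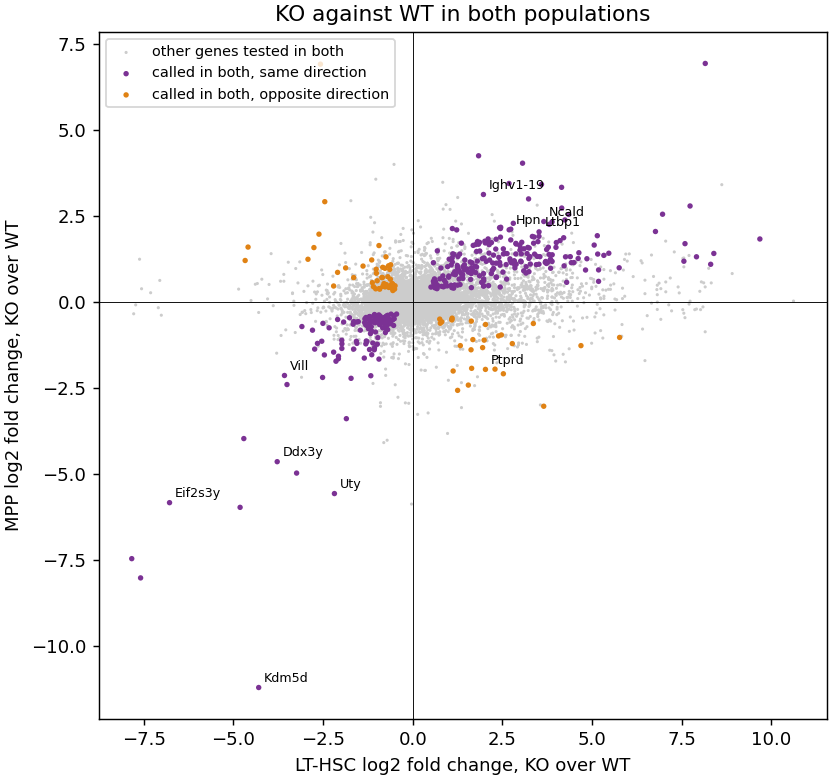
Log2 fold change KO over WT in LT-HSC (horizontal) and MPP (vertical) for the 13747 genes tested in both; purple marks the 224 genes higher in both and the 129 lower in both, orange the 27 and 47 called in opposite directions, grey the other genes. The 10 named genes are labelled; fitted values of genes with 3 or fewer counts in a group depend on the prior count.

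The interaction of population and genotype asks where the KO effect itself differed. Erythroid genes rose more in LT-HSC than in MPP, with a median difference of 1.64 and 13 of 15 genes passing (camera adjusted p = 1.2e-17, adjusted p = 0.0259 with an estimated correlation). The difference was 2.61 (SE 0.26) for Klf1. Immediate early and heat shock genes differed the other way, with a median difference of -0.84 and 15 of 22 genes passing (adjusted p = 5.38e-15, adjusted p = 0.168 with an estimated correlation), and Klf2 at -2.35 (SE 0.15). Ccne1 differed by 3.02 (SE 0.20), Cdkn1a by -1.35 (SE 0.20), Vwf by -1.60 (SE 0.23) and Ighg3 by -4.52 (SE 0.35). Tet1 differed by 0.53 (SE 0.23, adjusted p = 0.133) and did not pass. Of 16551 genes tested, 2256 had a higher and 1407 a lower KO effect in LT-HSC (3633 and 3270 with the replicate number as a block). With the LT-HSC background subtracted, 1270 were higher, and the counts were 798 and 334 without MPP WT replicate 2, 1211 and 487 without MPP WT replicate 1, 1026 and 419 without MPP KO replicate 1, 1269 and 629 without MPP KO replicate 2 and 1431 and 710 without LT-HSC KO replicate 1.

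The comparison of WT LT-HSC with WT MPP checks that each population carries the genes its label names. Stem cell genes were higher in LT-HSC: 22 of 26 identity genes passed with a median log2 difference of 1.82, such as Slamf1 at 2.73 (SE 0.19) and Procr at 2.34 (SE 0.16). Megakaryocyte genes were higher in 10 of 11 cases and interferon response genes in 16 of 25. MPP and early lymphoid priming genes were lower in LT-HSC in 10 of 12 cases, with Flt3, a receptor of multipotent progenitors, at -3.88 (SE 0.13) and Dntt, which encodes an enzyme of antigen receptor rearrangement, at -6.21 (SE 0.18). B lineage genes were lower in 19 of 20 cases and granulocyte and monocyte genes in 17 of 19, with Elane at -6.77 (SE 0.21) and Mpo at -6.61 (SE 0.17). Camera adjusted p-values were at most 6.69e-05 for these 6 lists. With an estimated correlation they were 0.0582 for the identity, priming and B lists, 0.122 for megakaryocyte, 0.132 for interferon and 0.12 for granulocyte genes. Of 14660 genes tested, 2544 were higher and 2478 lower in LT-HSC WT, and without MPP WT replicate 2 these counts were 1288 and 1176 (1308 and 1313 without MPP WT replicate 1).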

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

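The KO effect differed between LT-HSC and MPP for many genes and lists, by the edgeR interaction test with Benjamini-Hochberg adjustment. Of the tests below, those of reads over gene bodies, of RNA of another cell type as the whole cause, of the background behind the erythroid and stromal rises, of the further erythroid and bone-lining lists and of shared B lineage priming were chosen after the result was seen, as was the subtraction of background. The list of antibody-secreting cell genes was also added after the data were seen.

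In LT-HSC the KO effect was higher for 2256 genes and lower for 1407. By camera, 12 lists differed, with median differences (LT-HSC minus MPP) of 1.64 for erythroid, 1.95 for endothelial and stromal, 2.11 for sex-linked, 0.342 for histone, 0.327 for cell cycle, -0.408 for LT-HSC identity, -0.89 for megakaryocyte, -0.839 for immediate early and heat shock, -0.327 for interferon response, -0.302 for Polycomb, -0.362 for lymphoma and -0.246 for cytokine receptor genes. With an estimated correlation the erythroid list alone passed, at an adjusted p of 0.0259.

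The rule for named genes favoured large changes within a population in these same libraries, which makes a difference between populations more likely. Over all genes 3663 of 16551 differed, and of the named genes tested 92 differed and 47 did not. Among those given here, the difference of log2 fold changes was above 0 for Fam19a2 5.82, Kcnd2 5.77, Hrsp12 5.47, Cr2 4.41, Ptprd 3.98, Uty 3.37, Lhfp 3.27, Axin2 3.25, Ccne1 3.02, Ermap 2.71, Klf1 2.61, Bank1 2.45, Car1 2.17, Ccne2 2.02, Rhag 1.68, Fancc 1.59, Ebf1 1.59, Hist1h1b 1.57, Col1a2 1.5, Ltbp1 1.49, Usp18 1.39, Ncald 1.32, Rrm2 1.24, Mbd4 1.2, Ccnb1 1.09, Hist1h2bb 1.05, Tspan33 0.89, Iigp1 0.80, Blm 0.74 and Flt3 0.70. It was below 0 for Sgk1 -0.61, Esam -0.73, Cbx7 -0.80, Phf1 -0.97, Gbp2 -0.97, Fancg -0.98, Ezh1 -1.01, Fos -1.08, Tnfaip3 -1.11, Itga2b -1.15, Bst2 -1.22, Cd48 -1.23, Phf19 -1.24, Csf2rb2 -1.30, Cdkn1a -1.35, Id3 -1.36, Jun -1.44, Vill -1.45, Vwf -1.60, Rsad2 -1.62, Pou2af1 -1.66, Treml1 -1.70, Mycn -1.73, Klf4 -1.85, Gadd45b -1.88, Pf4 -1.97, Cd79b -2.16, Klf2 -2.35, Ncf4 -2.38, Fzd8 -2.40, Igkv8-27 -2.41, Klrb1c -2.48, Gp1bb -2.62, Nkg7 -2.78, Egr2 -2.90, Ighg3 -4.52, Ighv1-61 -4.63, Ighv7-3 -5.53, Ighg1 -7.60 and Ighv2-6 -9.49. For genes with 3 or fewer counts in a group, where a fitted difference depends on the prior count, the edgeR adjusted p of the difference was 0.00214 (Prg4), 0.00243 (Col1a1), 0.00382 (Ccnb1ip1), 0.00512 (Ngp), 0.0053 (S100a8), 0.0173 (Cxcl12), 0.00547 (Kdm5d), 0.00585 (Fstl4), 0.00152 (Slc6a20a), 0.0075 (Fcgr3), 0.0122 (Cnbd1), 0.0263 (Tmeff2), 0.0147 (Cd2), 0.0214 (Lef1), 0.0151 (Blk), 0.0079 (Ighv1-85), 0.0334 (Ighv1-47), 0.0236 (Igkv2-109) and 0.000228 (Igkv4-72). With the LT-HSC background subtracted, 71 of these 92 differences held, Fstl4, Fam19a2 and Tmeff2 had too few counts left for a test, and 15 calls ended, the differences becoming Kcnd2 6.78 (SE 2.01), Esam -0.58 (SE 0.19), Blk 2.73 (SE 1.66), Itga2b -0.98 (SE 0.31), Fancc 0.98 (SE 0.36), Gbp2 -0.83 (SE 0.26), Phf1 -0.81 (SE 0.25), Id3 -1.27 (SE 0.42), Lef1 5.54 (SE 3.04), Csf2rb2 -1.26 (SE 0.36), Ighv1-47 -5.69 (SE 1.63), Sgk1 -0.58 (SE 0.20), Axin2 2.87 (SE 0.94) and Ptprd 0.82 (SE 0.46), with no usable spread for Kdm5d. The sign reversed for Ebf1 -0.76 (SE 0.50), and for Ncald, with no usable spread. It also reversed for Uty (-5.40), but the background expected over its span exceeds its LT-HSC KO counts (34 and 35). The subtraction leaves no counts there, so that value depends on the prior count and is no measured reversal. The background is expected to give 102% of the LT-HSC excess of Fam19a2, 86.8% of Kcnd2, 112% of Ptprd and 107% of Ebf1.

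Genes that are hardly expressed in MPP rose broadly in LT-HSC KO. RNA of another cell type as the whole cause would raise only that type's genes, but 85.1% of the 1225 genes with at most 10 MPP counts that differed were higher in KO (1043 genes). This share is a measure of the flagged rise itself and no separate test. For loss of Tet1 raising silent genes in both populations, the chosen limit was over 60% higher in MPP KO. This was among genes with at most 10 counts in LT-HSC WT that differed at all, scaled to library totals only. The share was 54.8% (95% exact binomial interval 53.1 to 56.5, taking genes as independent). It is below the limit, but more of these genes were higher than lower (1851 of 3380 higher), so a smaller rise in MPP is not excluded. The genes were chosen on LT-HSC WT counts alone and were not required to be silent in MPP. Immunoglobulin and other genes that rose in MPP KO can be among them. The share can therefore not tell a rise of silent genes from those rises. Reads from genomic DNA or unspliced RNA are a candidate source: among the 4 longest of 8 span classes the KO counts per kb differed by at most 1.38-fold. What remains open is whether these reads reflect an unnamed difference in preparation or a property of KO cells (both groups started from 10000 cells), since genotype and background coincide in all 4 libraries. The share of the satellite-rich genes was far smaller in MPP but also higher in KO (0.00574% and 0.00572% against 0.0033% and 0.00313% in WT).

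Erythroid and stromal genes rose in LT-HSC KO. The background over gene bodies as the whole cause is argued against for the erythroid rise, where it gives a median of 0.223% of the KO excess (0.0107 to 2.08% over 15 genes); for the stromal rise it gives 27.8% (0.358 to 136% over 8 genes), and it is argued against there too, since 62.5% of the members that rose (5 of 8) still rose with it subtracted, and Flt1, Col3a1 and Cdh5 had too few counts left. Erythroid cells or their RNA are a candidate source, since 81.8% of a further erythroid list rose (18 of 22, 95% exact binomial interval 59.7 to 94.8; 16 of 20 members not seen before; 2 of its 25 genes are in fixed lists and 21 are expressed in LT-HSC WT; camera adjusted p = 7.53e-18, and 0.0825 with an estimated correlation), with Hba-a1 at 675.3 and Hbb-b1 at 391 CPM in KO. Bone-lining cells are a candidate source of the stromal part: 87.5% of the tested osteoblast genes rose (7 of 8, interval 47.3 to 99.7, 6 of 7 not seen before). Only 8 of the 14 list genes in the deposited table had enough counts for a test. Members silent in WT could enter it only if high in KO. This share, its interval and the camera test can therefore overstate the rise (camera adjusted p = 7.85e-06, and 0.0962 with an estimated correlation). Of the 15 list genes, 3 are expressed in LT-HSC WT. With background subtracted 5 of the 7 still rose and 2 had too few counts left. Col1a1 was at 271 CPM in KO. Flow sorting should remove both cell types, and its gates are not given in the sources used here. A change in the KO stem cells themselves stays open and untested.

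Immunoglobulin transcripts rose in MPP KO. A rise of B lineage priming shared by the KO cells stays open: 12.2% of the 205 tested segments fell, but reads divide among segments in an uncertain way, and Pou2af1, Vpreb1, Igll1, Blnk and Il7r rose. Antibody-secreting cells are a candidate source, since 82.4% of a list of their genes rose (14 of 17, 95% exact binomial interval 56.6 to 96.2; 0 of its 19 genes are in fixed lists and 17 are expressed in MPP WT), with Ighg3 at 1366 CPM in KO. Flow sorting should remove such cells. A different set of B lineage clones after transplant, an effect of Tet1 loss on antibody-secreting cells, or both, stays open and untested.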

How the results depend on the processing

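Alternatives were planned except the subtraction of background, the background limit, leaving out Gm16869, Gm10800 and Gm10801, leaving out immunoglobulin genes and centring the median, which were chosen after the data were seen. The LT-HSC counts (3529 higher, 1717 lower) became 1277 and 724 with a mean of at least 50 counts, 1298 and 850 with background subtracted and 449 and 303 with background under 10%; the lower count became 4009 with the replicate number as a block, 3024 with all 8 libraries in 1 fit, 572 at an adjusted p under 0.01 and 710 at 2-fold. Leaving out 1 library gave 1946 to 4213 and 379 to 2543. The MPP counts (707, 366) became 397 and 178 with no filter, 3536 and 3698 with the block, 352 and 148 in 1 fit, 140 and 34 at 0.01, 1314 and 912 at 0.1, and 384 and 151 at 2-fold, and 0 to 213 and 0 to 55 leaving out 1 library. The 0 counts are edgeR's without either MPP WT library, where 2119 and 2220 genes had an unadjusted p under 0.05 and DESeq2 called 219 and 42, and 203 and 53. Genes higher (224) and lower (129) in both populations became 139 and 72 with no filter, 137 and 84 with a mean of 50, 1078 and 1513 with the block, 34 and 15 at 0.01 and 422 and 311 at 0.1. Those lower became 82 in 1 fit, those higher 138 with background subtracted, and leaving out 1 library gave 0 to 239 and 0 to 138. The interaction counts (2256, 1407) became 3633 and 3270 with the block, 1241 and 827 with a mean of 50 and 716 and 320 at 0.01; those higher became 1270 with background subtracted, those lower 2199 at 0.1 and 696 at 2-fold, and leaving out 1 library gave 798 to 2521 and 334 to 1716. WT LT-HSC against MPP (2544, 2478) became 4038 and 3781 with the block, 1102 and 1096 at 0.01, and 1288 to 3372 and 1176 to 3697 leaving out 1 library. Lists called higher and lower became 0 and 0 with an estimated correlation in both populations (from 2 and 8 in LT-HSC and 4 and 2 in MPP; camera, with 3 lists at an unadjusted p under 0.05 in each). LT-HSC lists called lower became 4 with background subtracted, as the interferon response, Polycomb, lymphoma and cytokine receptor lists no longer passed (adjusted p = 0.0962, 0.314, 0.0992 and 0.0615), while the cell cycle list passed (0.000163), and MPP lists became 2 and 1 with fry; leaving out 1 library gave 2 and 7 to 10 in LT-HSC and 4 to 6 and 2 to 3 in MPP. Subtracting background reversed Ebf1 (-0.359) and Ptprd (-1.12) in LT-HSC, where 63 named calls held, 16 ended and 14 had too few counts left for a test. DESeq2 kept 86 of 96 LT-HSC and 66 of 72 MPP values. Libraries with the same number shared deviations (r = 0.49 to 0.704 over 6 pairs of groups), a hint of pairing or of shared handling. The main fits do not model it. A group left with 1 library is assumed to vary like the others. Pseudocounts, scalings of normalized values, random lists and limma tests of single genes, planned for other units, were not run on these counts.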

Other observations

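Members of the X-linked Xlr family, genes of lymphocytes and germ cells that lie in clusters and share sequence, were lower in KO in both populations: 6 of 9 fell in LT-HSC and 8 of 9 in MPP, with medians of -1.98 and -1.65. This family was chosen after its values were seen. Xlr itself had 0 counts in all KO libraries, against 27 and 21 in LT-HSC WT and 30 and 35 in MPP WT, and Xlr3a had 0 and 1 against 18 and 17 in LT-HSC and 1 and 0 against 41 and 38 in MPP. Xlr4a had -2.74 (SE 0.46) and -1.37 (SE 0.15). Copies are near-identical, so how reads divide among them is uncertain. The X chromosome as a whole did not follow: 162 of 741 X-linked genes rose and 55 fell in LT-HSC, and 13 of 719 rose and 17 fell in MPP.

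The lists added later also gave counts in the other population. In LT-HSC KO, 1 of 14 antibody-secreting cell genes rose and 4 fell, and 5 of the 8 germline genes tested rose (adjusted p = 0.189 for each by camera with an estimated correlation). The germline list has 13 genes in the deposited table. Its rise is not set against the background, which accounts for a median of 56.1% of the excess of all genes called higher in LT-HSC KO. Osteoblast genes had a median of 4.07 there with genes at 0 counts set to their bound: Col11a1 was at least 58.4-fold, Bglap2 23.4-fold, Ibsp 18.4-fold and Dcn 15.4-fold higher. The background is expected to give 64.9%, 0.823%, 13.4% and 50% of their excess, and with it subtracted Col11a1, Bglap2 and Ibsp still rose while Dcn had too few counts left for a test. In MPP KO, 8 of 22 further erythroid genes rose (adjusted p = 0.0539 with an estimated correlation), as did 3 of 5 osteoblast genes (0.066), among them Postn at 37 counts against 2 (ratio 18.8, 95% interval 4.84 to 161). The antibody-secreting list passed in MPP with an estimated correlation (adjusted p = 0.0283).

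Genes called in the same direction in both populations were set against 2 explanations, with both tests chosen before their results were seen. Genes linked to Tet1 and carried over from the strain of the targeted cells could be shared for that reason. Of 85 genes within 10 Mb of Tet1, 4 were among the 353 shared genes, 1.83 times the share among all genes (odds ratio 1.88, 95% interval 0.498 to 5.05, Fisher's exact test p = 0.175). These were Cdh23, Adamts14, Gm5424 and Tspan15, which start at 59765496 to 61648144 on chromosome 10, all on 1 side of Tet1. A narrower window was not tested, and too few genes decide it. Lower germline gene expression in KO was seen in 0 of 7 germline genes in MPP (95% exact binomial interval up to 41%; 1 at an unadjusted p under 0.05 and lower, 0 by DESeq2), where 1 rose. Sex was not tested as a cause of the shared calls. The Y-linked genes differ with genotype in both populations, so an effect of sex cannot be told apart from one of genotype.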
